A study of Mus musculus with 5 samples.

How the data were processed

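The series holds 3' single-cell RNA-seq (10x Genomics, version 3.1 chemistry) of 3 bone marrow libraries and 1 spleen library, labelled as from Tcf7 reporter mice, and the hashtag antibody counts of the spleen cells. The deposited values are raw UMI counts per gene and barcode, made with Cell Ranger 6.1.1, STAR 2.7.2a and bcl2fastq 2.20.0 against build mm10, per the submitters' processing notes. CPM are UMI counts scaled by a group's total. The annotation release is not given in the sources used here, and no genome was used, so genes carry the symbols that the deposited feature tables pair with gene identifiers, and no coordinates are given. A deposited text table names the population that each of 3 hashtags labelled: ALP-derived, ENKP-derived and ILCP-derived NK cells.

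Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept, and doublets called by Scrublet in each library were removed. Of 4937, 1301 and 6720 barcodes in the ILC progenitor, CD122+ and NK and ILC1 libraries, 4100, 1150 and 5796 cells remained, and of 4736 spleen barcodes 1841. Total UMIs per library were 71087358, 27131931, 43183825 and 11261733. Scrublet removed 9, 5, 112 and 5 barcodes (0.219%, 0.433%, 1.90% and 0.271%). These are low shares, so undetected doublets remain open. In the spleen library 39.0% of barcodes passed, and the median mitochondrial share over all its barcodes was 10.9%. Hashtags were called with HTODemux of Seurat 5.3.0 (centred log ratios, positive quantile 0.99), which set thresholds of 187, 87 and 125 counts. It called 141 of the spleen barcodes doublets and 224 negative, and these were left out.

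Cells were scaled to 10000 counts, log-transformed and reduced to 30 principal components of 2000 variable genes with scanpy 1.11.5. Graphs of shared neighbours (15 per cell, Jaccard weights) were clustered with leidenalg 0.10.2 (seed 0), the bone marrow libraries together at resolution 1 and the spleen library alone at resolution 0.6. Clusters were named from 17 fixed marker lists. A marker counted in a cluster at 20 CPM or more and at least 2-fold above the other cells, with 5 CPM added to both. A cluster took the name of the list with the largest share of such markers. It stayed unnamed with fewer than 3 of them, with a tie, with more markers of another class among its 10 leading genes, or with at least 3 of 8 macrophage genes among those. A cluster with all cycling markers was called cycling. The cycling and pan-NK lists gave no names. Clusters named for 6 lineages (B, T, granulocyte and monocyte, dendritic, erythroid, and basophil and mast cells) are called other lineages. Clusters 5, 11 and 13 took the immature NK name, but cluster 11 did so by a narrow margin (6 of 10 markers, against 7 of 12 mature NK markers) and joined the mature NK-like cells under most other settings, so these clusters are given by number.

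Each group is 1 library or 1 hashtag, so the edgeR test foreseen for at least 2 animals per origin was not run, and no p-value is given. UMIs were summed over the cells of a group and scaled to CPM. CPM have exact Poisson intervals, ratios of CPM exact conditional binomial intervals and shares of cells Clopper-Pearson intervals, at 95% and for counting error only. A group at 0 counts enters a ratio at a floor of 3 counts, and the upper limit given for a share of 0 is likewise 3 cells of the total, not the Clopper-Pearson bound. Genes at 50 CPM or more in 1 group were counted at a ratio of at least 4 between bone marrow libraries and of at least 2 between spleen origins and within classes. The genes named are the 12 with the largest and the 12 with the smallest ratio at 100 CPM or more in 1 group, leaving out mitochondrial and ribosomal protein genes, immunoglobulin and T cell receptor segments, Xist and Y-linked genes. Members of the fixed lists and markers are named as examples, and Tcf7 and Il2rb in every bone marrow library. The 11 gene lists are cytotoxic effectors, cytokines and chemokines, Ly49 receptors, other NK receptors, cytokine receptors, homing and adhesion, lymphoid transcription factors, cell cycle, immediate early and dissociation stress, interferon response, and mTORC1, MYC and glycolysis. A member counts as measured at 20 CPM or more in 1 group and as higher or lower at a ratio of 2. A list's median has its percentile among 10000 random lists matched on mean expression (bins of 50 genes). Shares of cells with a regulator were taken after thinning each cell to 2000 UMIs, which left out 54, 5 and 86 shallower cells of the bone marrow libraries.

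The groups, markers, gene lists, filters, comparisons of libraries and origins, and most alternatives were fixed before the data were examined. Chosen after seeing the data were the details of the naming rule with its macrophage list, the ratio of 2 for the spleen and for classes, the comparisons within classes and in cluster 5, the comparisons between classes of 1 library, the naming of genes again without other lineages (leaving them out was planned), the threshold of 20 UMIs of 6 genes that marks cells rich in granulocyte transcripts, the thresholds for hashtag counts in the ILC progenitor library and for spleen barcodes left out, and which class and regulator shares count as main results. Alternatives fixed beforehand were TMM factors (edgeR 4.0.16) and median ratio size factors (DESeq2 1.42.0) as scalings, the mean of per-cell CPM, no expression floor, all deposited barcodes, other lineages or cycling clusters left out, thinning, other clustering and doublet settings, and other hashtag rules. Added after seeing the data were relaxed quality control of the spleen cells (500 UMIs, 250 genes, 25% mitochondrial UMIs), leaving out cells rich in granulocyte transcripts, size factors and per-cell means for the spleen, and the alternatives within classes.

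The computation was tested on simulated counts with the real means and totals and 200 genes changed. In the comparisons of CD122+ with ILC progenitors (2802 genes) and with NK cells and ILC1s (2867 genes), 100 of 100 genes changed 8-fold were counted in each, and 0 of 100 changed 3-fold, since the threshold is 4. In the comparison of ENKP-derived with ILCP-derived cells (3517 genes), 100 of 100 were counted at 8-fold and 100 of 100 at 3-fold. In each, 0 unchanged genes were counted, and the intervals covered the true ratio for 95.4%, 95.4% and 95.2% of unchanged genes. The summed counts were drawn as Poisson, as the intervals assume, without variation between cells. These values therefore check the computation and say nothing about the spread of real cells. A simulated list of genes changed 3-fold was at percentile 100 in each, and lists of unchanged genes at 50.0, 50.6 and 77.8. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.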

Results

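Single-cell RNA-seq was performed on progenitors and mature cells of the innate lymphoid cell (ILC) and natural killer (NK) lineages of mice aged 6 to 18 weeks that carry a yellow fluorescent reporter of Tcf7, the gene of the transcription factor TCF-1. Bone marrow gave 3 libraries: ILC progenitors (a sort labelled as ALP, EILP, ILCP and ILC2P), progenitors positive for CD122 (the interleukin-2 and interleukin-15 receptor subunit encoded by Il2rb), and mature NK cells with group 1 ILCs (ILC1s). The remaining library held spleen NK cells recovered from NSG mice, which lack lymphocytes of their own, after transfer of ALP, ENKP or ILCP cells. The spleen cells of the 3 origins were labelled with a hashtag antibody each and captured together. After quality control 4100 cells of the ILC progenitor library, 1150 of the CD122+ library and 5796 of the NK and ILC1 library remained, with 69109044, 26469720 and 41043462 UMIs and medians of 14156.5, 18571 and 5452.5 UMIs per cell. The spleen library gave 778 ALP-derived, 544 ENKP-derived and 431 ILCP-derived cells with 2697202, 1965610 and 1812471 UMIs and medians of 1916, 2015.5 and 2842 UMIs per cell. Each group was 1 library or 1 hashtag, so no difference below has a replicate check or a test. Intervals are 95% intervals and cover counting error only.

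The bone marrow libraries were clustered together to ask which cell types each sort held. In the ILC progenitor library 44.7% of cells (95% interval 43.2 to 46.2) were ALP-like, 29.1% (27.7 to 30.5) ILC2 progenitor-like, 11.7% (10.8 to 12.8) EILP-like and 5.95% (5.25 to 6.72) ILCP-like. The CD122+ library was 17.5% EILP-like (15.3 to 19.8), 16.3% ILCP-like (14.2 to 18.5) and 3.13% ALP-like (2.2 to 4.31), and 1 of its cells was ILC2 progenitor-like. The EILP name rests on 3 of 7 markers (Tcf7, Tox and Nfil3), the fewest that give a name, whereas the ILCP name rests on 10 of 10. The ILC2 progenitor-like cluster was named on 9 of 11 markers, with Il1rl1 in 994 and Gata3 in 1119 of its 1194 cells. Of its 10 leading genes 5 were genes of bone-forming cells (Col1a1, Col1a2, Bglap, Bglap2 and Sparc), which were detected in 3 to 9 of these cells, and for each gene the 3 highest cells held 99.88% or 99.89% of its UMIs (Bglap, Col1a1) or all of them. Antibody genes that led the largest ALP-like cluster (Iglc1, Ighg2b and Jchain) likewise had at least 99.6% of their UMIs in the 3 highest of its 1269 cells. T cell-like cells, with the CD3 genes Cd3d, Cd3e and Cd3g and the T cell receptor gene Trac, made up 34.3% of the CD122+ library (31.6 to 37.2), 3.23% of the NK and ILC1 library and 0.756% of the ILC progenitor library. The name rests on these 4 of 8 markers. The larger cluster (474 cells) had Trac in 51.9% and the delta and gamma receptor genes Trdc and Trgv2 in 60.1% and 58.0%. The smaller, cycling cluster (139 cells) was led by Ccr10. It had Cd3g in 79.9%, Cd3d in 51.1%, Cd3e in 48.9% and Trac in 46.8%. Granulocyte and monocyte-like cells made up 8.0% of the CD122+ library, 4.87% of the NK and ILC1 library and 2.15% of the ILC progenitor library, and erythroid-like cells 5.39%, 1.35% and 2.63%. The erythroid-like cluster (248 cells) had Car2 in 85.9% and Klf1 in 49.2% of cells, but the globin gene Hbb-bs in 16.5%. The 3 highest cells held 65.5% of the Hbb-bs UMIs. In this cluster 5 basophil and mast markers counted too. The NK and ILC1 library was 43.4% mature NK-like (42.1 to 44.7) and 27.2% ILC1-like (26 to 28.3), with 1 EILP-like and 0 ILCP-like cells, a count of 0 that allows up to 0.0518%. Clusters 5, 11 and 13, which carried immature NK markers, are given by number. In cluster 13 these were 3 of 10 markers. Cluster 5 held 9.83% of the CD122+ library (8.17 to 11.7), 6.11% of the NK and ILC1 library and 0.390% of the ILC progenitor library, and cluster 13, which was cycling, held 3.39%, 1.62% and 0.537%. Cluster 11 was found in the NK and ILC1 library alone, at 4.43%. The sort gates are not given in the sources used here and can set these shares. An unnamed cluster with mature NK and T cell genes held 6.69% of the NK and ILC1 library and 0.348% of the CD122+ library. The T cell and ILC1 names depend on the naming rule: with doublets kept the T cell share of the CD122+ library was 9.78%, because its larger T cell cluster tied with another class, and with at most 5% mitochondrial UMIs the ILC1 share was 1.57%.

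**Figure D1:**
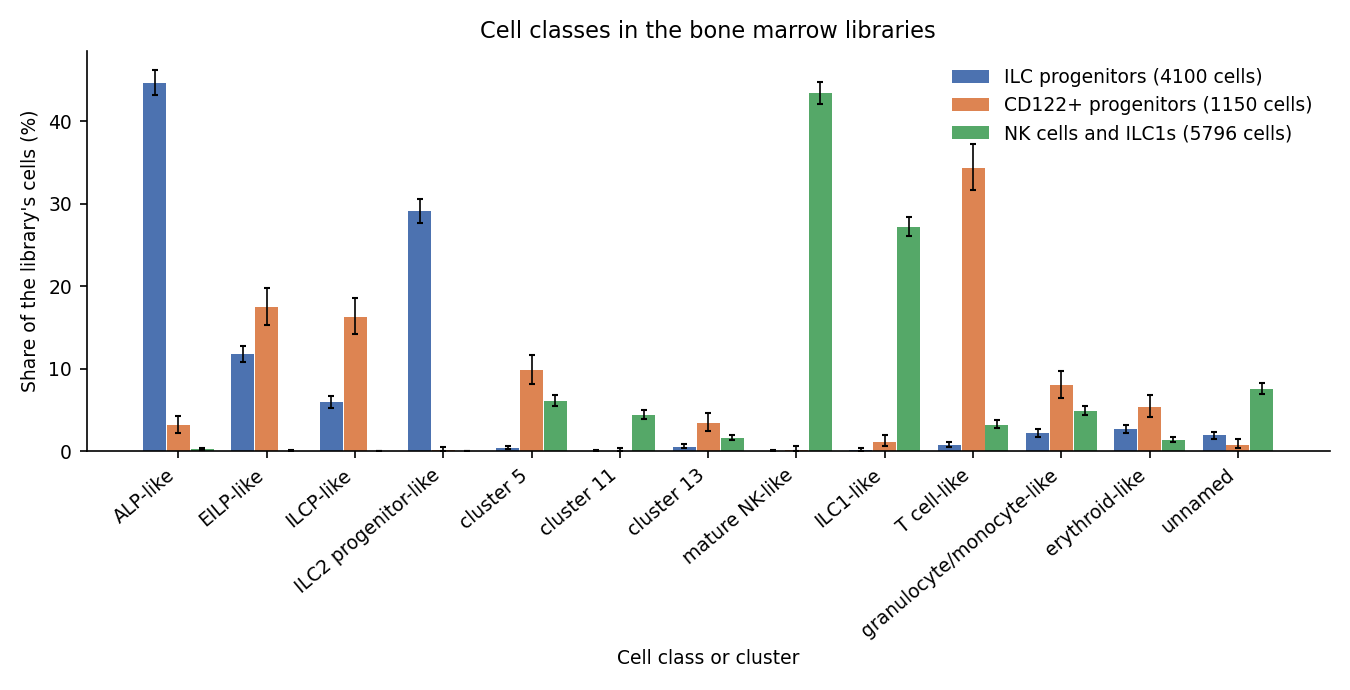
Share of each bone marrow library's cells (percent, vertical axis) in each cell class or cluster (horizontal axis), with exact binomial 95% intervals as error bars. ALP-like cells led the ILC progenitor library at 44.7%, T cell-like cells the CD122+ library at 34.3% and mature NK-like cells the NK and ILC1 library at 43.4%.

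The CD122+ progenitors were compared with the ILC progenitors to ask which transcripts set the CD122+ sort apart. Il2rb was at 229 CPM in the CD122+ library and 8.93 CPM in the ILC progenitor library, 25.6-fold higher (23.6 to 27.9). Tcf7 was at 378 and 94.1 CPM. The NK genes Klrk1 (NKG2D; 195 against 2.76 CPM) and Gzma (granzyme A; 458 against 4.99 CPM, 91.8-fold, 82.5 to 102) were higher in the CD122+ library, as were Cd7 (29.7-fold), Ms4a4b (35.1-fold) and the T cell gene Cd3d (132 against 4.15 CPM, 31.8-fold). Cells of other lineages made up 47.7% of the CD122+ library and 5.54% of the ILC progenitor library, so they enter these ratios. All 4 measured T cell markers were higher, with log2 ratios from 4.91 to 5.31. Granulocyte genes had the largest ratios: S100a9 was at 2091 against 0.854 CPM, S100a8 at 1847 against 8.84 CPM, and Camp at 619 CPM against 4 UMIs. They rested on 19 of the 1150 CD122+ cells, which held 99.7% of the UMIs of 6 granulocyte genes, and 7 of the 8 measured granulocyte and monocyte markers were higher. Dntt, which adds bases at antigen receptor gene junctions, was 56.7-fold lower (17.3 against 984 CPM), and lower too were the early progenitor genes Flt3 (8.18-fold, 24.4 against 199.6 CPM) and Cd34 (3.85-fold), Irf8 (3.42-fold) and Bcl11a (3.24-fold). Of 3059 genes at 50 CPM or more in 1 of the libraries, 54 were at least 4-fold higher in the CD122+ library and 15 at least 4-fold lower.

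The comparison was repeated without the clusters of other lineages (T, granulocyte and monocyte, and erythroid cells), which left 601 CD122+ and 3873 ILC progenitor cells. These differed in class mix: clusters 5 and 13 held 152 of the CD122+ cells and 38 of the ILC progenitor cells. ALP-like cells numbered 36 and 1832, and ILC2 progenitor-like cells 1 and 1193. The ratios below pool these classes, so the class mix enters them. Of 3077 genes, 48 were then at least 4-fold higher in the CD122+ cells and 27 lower. Ncr1, the NK receptor NKp46, led at 117 against 0.519 CPM (226-fold, 159 to 331), followed by Klrk1 (90.7-fold, 77.6 to 107), Cd7 (24.4-fold), Il2rb (23.7-fold, 21.6 to 25.9), the calcium-binding protein gene S100a4 (12.9-fold), the cathepsin gene Ctsw (8.11-fold), Klrd1 (7.69-fold) and the kinase gene Txk (7.51-fold). Among 11 measured NK receptors other than the Ly49 family, 10 were at least 2-fold higher and 0 lower, with a median log2 ratio of 4.80. Of 8 cytotoxic effectors 5 were higher, among them Gzma (log2 4.09) and Ctsw (3.02), and Cst7 was lower (−1.50). Lymphoid transcription factors went both ways. Of 26 measured, 14 were higher, including Tbx21 (T-bet, log2 6.35), Eomes (4.44), Tcf7 (2.51), Zbtb16 (PLZF, 2.29), Id2 (2.04) and Runx3 (1.88). Lower were 8, including Zeb2 (−2.69), Notch1 (−1.95) and Bcl11a (−1.70). Within the CD122+ library, Tbx21 was detected in 60.5% of the cells of clusters 5 and 13, 1.99% of EILP-like and 11.2% of ILCP-like cells. Eomes was detected in 21.7%, 16.4% and 9.09%, all without thinning. The medians of the NK receptor, cytotoxic and transcription factor lists were at percentile 100 among 10000 random lists matched on expression. Chemokine receptors and adhesion genes had 7 of 15 higher (Cxcr3 5.68, Cxcr5 2.77, Ccr2 2.27) and Ccr9 lower (−3.45). Of 16 cytokine receptors, Il2rb (4.57) and Il18r1 (2.49) were among 4 higher, and Il1rl1 (−3.37), Il2ra (−3.31) and Flt3 (−2.67) among 5 lower. All 3 measured cytokine genes were higher, the 20 cell cycle genes and the 13 mTORC1, MYC and glycolysis genes all stayed within 2-fold, 2 of 5 interferon response genes and 2 of 7 immediate early genes were lower, and 0 Ly49 genes were measured. Dntt (35.6-fold), Il12a (13.4-fold), Flt3 (6.38-fold) and Cd34 (4.71-fold) were again lower.

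The CD122+ progenitors were next set against the mature NK and ILC1 library. The CD122+ library had more of the progenitor transcription factor genes Hes1 (108 against 4.75 CPM, 22.6-fold), Sox4 (11.8-fold), Zbtb16 (144 against 13.3 CPM, 10.8-fold, 9.86 to 11.8), Tcf7 (378 against 75.4 CPM, 5.02-fold, 4.82 to 5.22) and Tox (5.0-fold), and of Igfbp4 (14.8-fold) and Lmo4 (5.62-fold). The mature library had more of the effector genes Prf1 (perforin; 501 against 3.89 CPM, 129-fold), Gzmb (9.86-fold), Gzma (4868 against 458 CPM, 10.6-fold), the mast cell protease gene Cma1 (751-fold), Klrb1c (NK1.1; 46.0-fold) and Klra8 (555-fold). Il2rb was at 886 CPM in the mature library. The myeloid granule gene Mpo was also higher in the CD122+ library (815 against 129 CPM, 6.30-fold), 5 of 8 granulocyte and monocyte markers and all 4 T cell markers were higher there, and 4 of 6 erythroid markers. Of 3333 genes, 35 were at least 4-fold higher in the CD122+ library and 77 lower. Cytotoxic effectors (0 higher and 7 lower of 11; median log2 −1.70), other NK receptors (1 and 15 of 18; −2.71), Ly49 receptors (0 and 5 of 6; −4.37) and cytokines (0 and 4 of 6; −2.96) were lower in the CD122+ library, homing and adhesion genes had 0 higher and 10 lower of 20, and cell cycle genes 12 higher and 0 lower of 20 (median 1.04). Of 29 transcription factors 11 were higher and 8 lower, among them Tbx21 (−2.28), Eomes (−2.11) and Prdm1 (−3.88). Cytokine receptors had 2 higher, Flt3 (2.67) and Kit (1.85), and 6 lower of 15, and immediate early genes 0 higher and 5 lower of 9. The 13 mTORC1, MYC and glycolysis genes stayed within 2-fold (median 0.51), as did the 7 interferon response genes, whose median (−0.56) turned positive when cells were weighted equally (0.37). The all-gene median was 0.05 on this scale and −0.15 with TMM scaling, and equal weight to each cell moved the split from 35 higher and 77 lower to 84 and 80.

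Without the other lineages (601 against 5249 cells) 77 genes of 3416 were at least 4-fold higher in the CD122+ cells and 155 lower. Tox2, a transcription factor gene of early ILCs and NK cells, was at 158 against 0.279 CPM (568-fold, 299 to 1244), and Hes1 (41.7-fold), Pdcd1 (PD-1; 24.9-fold) and Zbtb16 (18.6-fold, 16.9 to 20.6) followed. Prf1 (214-fold), Fasl (194-fold), Gzmb (90.1-fold), the integrin gene Itgam (75.0-fold) and Gzma (64.6-fold) were lower. All 7 Ly49 genes (median −5.37) and 16 of 17 other NK receptors were lower, and 14 of 20 cell cycle genes were higher (median 1.31). The 3 measured T cell markers were lower here (median −2.62), but the filter itself shaped this direction. It removed the T cell-like cells of both libraries and kept the unnamed cluster with mature NK and T cell genes. That cluster held 388 NK and ILC1 cells and 4 CD122+ cells.

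**Figure D2:**
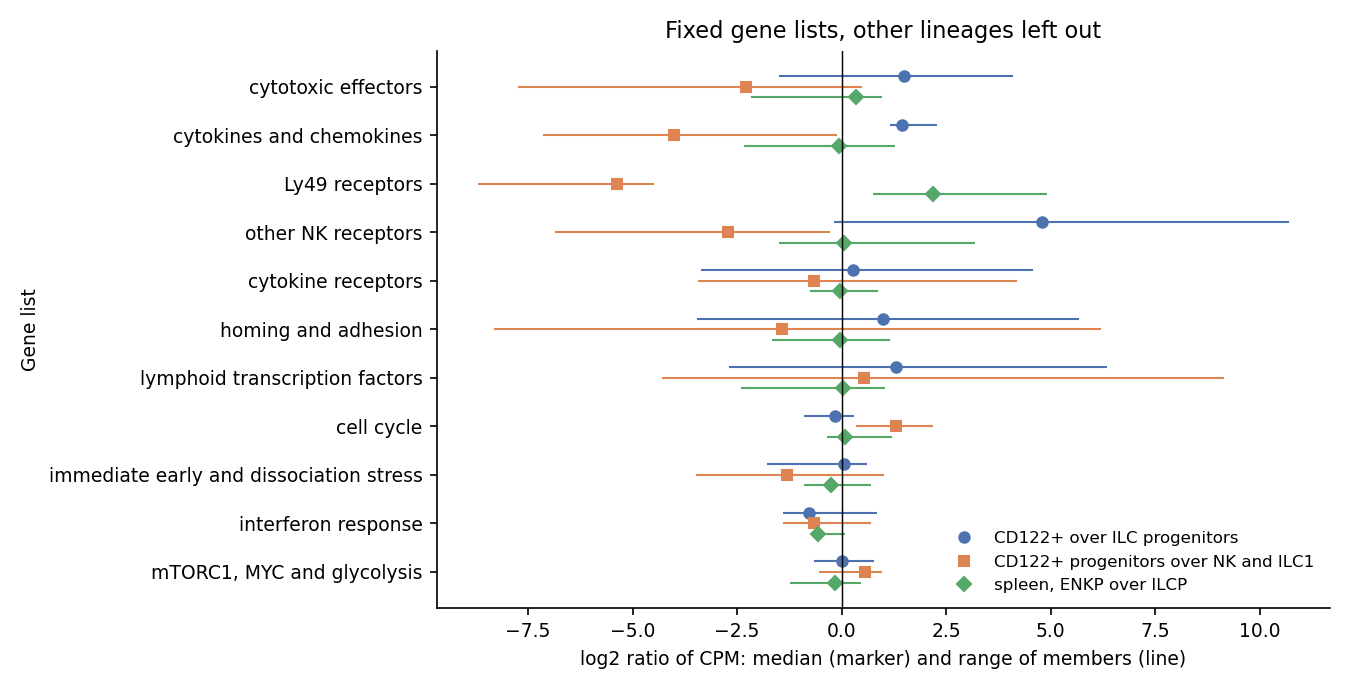
Median log2 ratio of CPM (markers) and range of the measured members (lines) for each fixed gene list (vertical axis), without the clusters of other lineages, in CD122+ over ILC progenitors, CD122+ progenitors over NK cells and ILC1s, and ENKP-derived over ILCP-derived spleen NK cells. The Ly49 list had a median of −5.37 in the CD122+ progenitors over NK cells and ILC1s, and of 2.19 in the spleen comparison.

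The ILC progenitor library and the mature library were the furthest apart of the sorts by number of genes. Dntt was 1063-fold higher in the ILC progenitors (984 against 0.926 CPM), Flt3 52.2-fold, Cd34 27.2-fold and Mef2c 11.2-fold. The inhibitory NKG2A gene Klrc1 (1 UMI against 199 CPM), Klrc2 (1 UMI against 325 CPM), Cma1 (1 UMI against 142 CPM), Klrb1a (2 UMIs against 187 CPM) and Gzmb (3 UMIs against 254 CPM) were nearly undetected in the ILC progenitors. Klra8 had 0 UMIs against 230.5 CPM and was at least 5310.0-fold lower, with 3 counts as the floor. Of 3397 genes 68 were at least 4-fold higher in the ILC progenitors and 221 lower, and without the other lineages 126 and 256 of 3442. All 17 other NK receptors (median log2 −7.58), all 6 Ly49 genes and 8 of 11 cytotoxic effectors (−4.24) were lower. Cell cycle genes had 11 of 20 higher (1.15). Transcription factors had 7 of 28 higher, including Tox2 (6.77), Mef2c (3.48), Bcl11a (3.25) and Zbtb16 (1.85), and 8 lower, including Tbx21 (−8.58) and Eomes (−6.18). Cytokine receptors had 5 higher (Flt3 5.71, Il17rb 4.61, Il1rl1 3.75) and 9 lower (Il2rb −6.63) of 18, and homing genes 2 higher (Ccr9 5.52) and 14 lower of 20. All 3 measured T cell markers and 6 of 8 granulocyte and monocyte markers were also lower in the ILC progenitors, and 4 of 5 dendritic markers higher.

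Whether single progenitors carried transcripts of ILC and NK regulators was read from the share of cells with a UMI after every cell was thinned to 2000 UMIs. In the 201 EILP-like cells of the CD122+ library Tcf7 was detected in 74.1% (67.5 to 80.03), Id2 in 54.2%, Zbtb16 in 32.8% (26.4 to 39.8), Il2rb in 30.4% (24.1 to 37.2), Eomes in 5.97% (3.12 to 10.2) and Tbx21 in 1 cell. In 480 EILP-like cells of the ILC progenitor library Tcf7 was detected in 50.8%, Id2 in 27.7%, Zbtb16 in 21.5%, Il2rb in 5.0% (3.23 to 7.35), Eomes in 0.417% and Tbx21 in 0 cells, which allows up to 0.625%. The ILCP-like cells had Zbtb16 in 68.4% (61.3 to 75.0; CD122+ library, 187 cells) and 58.0% (ILC progenitor library, 238 cells), Id2 in 95.7% and 96.6%, Il2rb in 26.7% and 10.1%, and Eomes in 4.28% and 0.840%. Tcf7 is a marker that named the EILP-like clusters, and Zbtb16 and Id2 are markers that named the ILCP-like cluster. High shares of these genes in those classes are therefore partly set by the naming. The sort on CD122 likewise favours cells with Il2rb in the CD122+ library. Granulocyte and monocyte-like cells, taken as background for Il2rb, Tcf7, Eomes and Tbx21, had each of these in 0 of 90 cells of the CD122+ library, which allows up to 3.33%, and Il2rb, Eomes and Tbx21 in 0 of 88 cells of the ILC progenitor library, which allows up to 3.41%. The Tbx21 shares of the EILP-like cells and the Eomes shares of the ILC progenitor library lay under these limits. The intervals of the Eomes shares of the CD122+ library and of the 5.0% for Il2rb included them, so at this depth those shares were not set apart from background. Granulocyte and monocyte-like cells were also the class set as background for Zbtb16. They are no clean background for it, since they carried it in 2.22% of cells at 2000 UMIs. ALP-like cells of the ILC progenitor library, not the class set for this gene, had Zbtb16 in 0.547% (0.263 to 1.003; 1829 cells). For Id2 the ALP-like cells served as background, with 4.76% (3.83 to 5.84) in the ILC progenitor library, below the 27.7% (23.75 to 31.95) of EILP-like cells, and 22.2% (10.1 to 39.2; 36 cells) in the CD122+ library, below 54.2% (47.1 to 61.3). Granulocyte and monocyte-like cells had Id2 in 7.95% and 11.1%. In the NK and ILC1 library Il2rb was detected in 76.6% of cells, Tbx21 in 20.6%, Eomes in 18.5% and Zbtb16 in 2.54%, against 1.44%, 1.44%, 0.361% and 2.89% of its granulocyte and monocyte-like cells. Before thinning, the EILP-like cells had medians of 22777 UMIs in the CD122+ library and 17770 in the ILC progenitor library, the ILCP-like cells 18916 and 10660, and the granulocyte and monocyte-like cells of the CD122+ library 39680. Unthinned, Il2rb was detected in 22.04% (18.4 to 26.01) of the EILP-like cells of the ILC progenitor library, against 1.14% (up to 6.17) of its granulocyte and monocyte-like cells. In the CD122+ library it was detected in 84.1% of the EILP-like cells and 3.26% of the granulocyte and monocyte-like cells, Zbtb16 in 70.1% and 23.9%, Eomes in 16.4% (11.6 to 22.3) and 1.09% (up to 5.91), intervals that do not overlap, and Tcf7 in 95% and 4.35%. With cells thinned to 2000 UMIs, Zbtb16 and Il2rb were detected together in 24 of the 201 EILP-like cells of the CD122+ library (11.9%, 7.80 to 17.2). The product of their shares at that depth was 9.97%. In the 187 ILCP-like cells of that library they were detected together in 29 (15.5%, 10.6 to 21.5), against 18.3%.

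**Figure D3:**
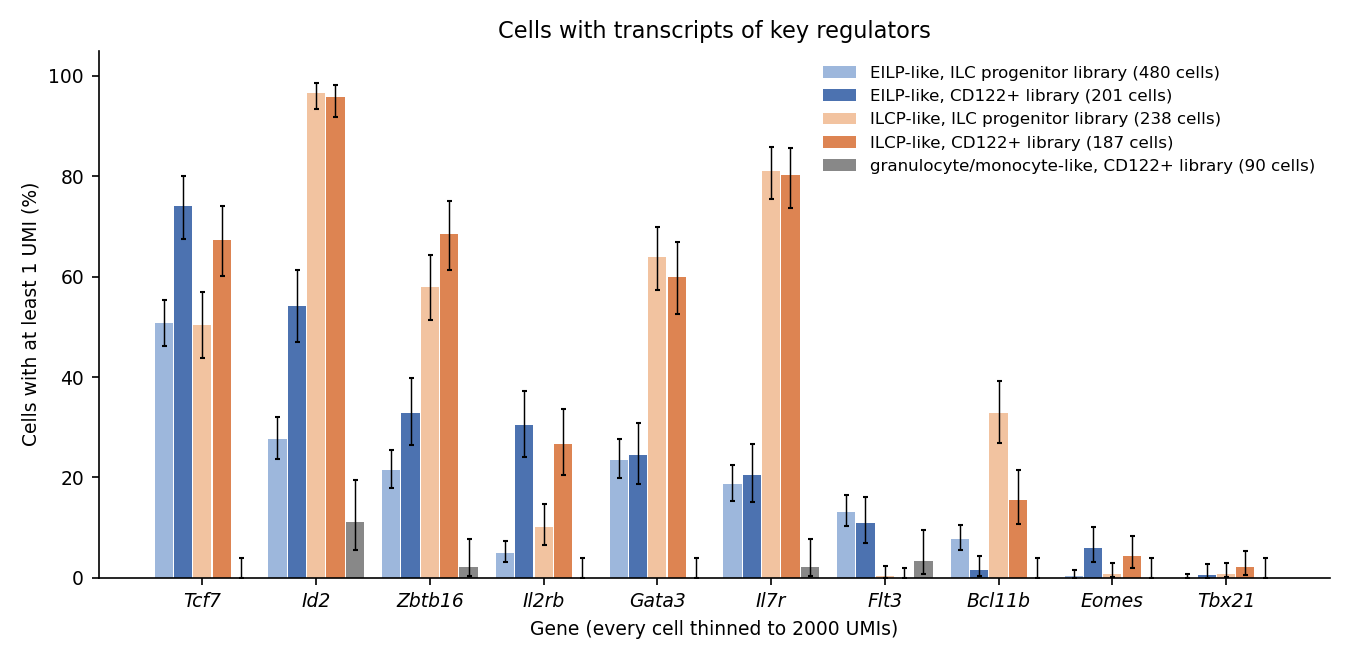
Share of cells with at least 1 UMI of each regulator (percent, vertical axis) after thinning to 2000 UMIs per cell, in EILP-like and ILCP-like cells of the ILC progenitor and CD122+ libraries and in granulocyte and monocyte-like cells of the CD122+ library, with exact binomial 95% intervals as error bars. Il2rb was detected in 30.4% of EILP-like cells of the CD122+ library and 5.0% of those of the ILC progenitor library.

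The same classes were then compared between the sorts. In EILP-like cells (201 CD122+ against 481 ILC progenitor cells) Il2rb was 9.25-fold higher in the CD122+ library (187 against 20.3 CPM, 7.92 to 10.8), S100a4 6.71-fold, Cd7 3.94-fold, Hes1 3.08-fold, Id2, an inhibitor of E proteins needed for ILC development, 2.75-fold and Runx3 2.40-fold. Mpo (7.05-fold), Dntt (4.14-fold), Cd34 (2.31-fold) and Irf8 (2.06-fold) were lower. Of 3011 genes 43 were at least 2-fold higher and 32 lower. Of 24 transcription factors 6 were higher (Eomes 3.04, Lef1 2.54, Maf 2.40) and 5 lower (Zeb2 −3.51, Bcl11b −2.49). In ILCP-like cells (187 against 244) 5 genes of 3092 were at least 2-fold higher and 6 lower. They had more Il2rb (138 against 64.0 CPM, 2.15-fold, 1.80 to 2.57), the growth factor gene Fgf15 (2.64-fold), Runx3 (1.67-fold) and Tcf7 (1.60-fold) in the CD122+ library, and less of the costimulatory gene Icos (3.91-fold lower), Bcl11b (2.09-fold) and Arg1 (1.94-fold). Klrk1 (log2 4.42) and Gzma (4.18) were also higher, whereas 21 of 22 transcription factors stayed within 2-fold. In cluster 5 the CD122+ cells (113 against 354) had less of Gzma (5.98 against 620.5 CPM, 104-fold), Klrb1c (11.4-fold), Ccl5 (6.08-fold), Xcl1 (5.38-fold) and Il2rb (381 against 1012 CPM, 2.66-fold) than the NK and ILC1 library, and more of Ccr10 (19.3-fold, 12.6 to 31.0), Tox2 (log2 4.15) and Zbtb16 (1.55). With 1 library per sort, the sort and the capture are confounded here. The counts moved with depth: with every cell thinned to 2000 UMIs 90 genes were higher and 84 lower in EILP-like cells, and 65 higher and 72 lower in ILCP-like cells.

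The spleen NK cells were compared by the progenitor transferred, to ask whether NK cells of different origin differ. Clustered without the Ly49 genes, 34.2% of ENKP-derived, 27.5% of ALP-derived and 16% of ILCP-derived cells were mature NK-like, and 11%, 14.7% and 29.9% immature NK-like, a name taken by a narrow margin (6 of 10 immature NK markers, against 6 of 11 ILC1 markers). With these genes the shares were 34.4% (30.4 to 38.5), 26.7% (23.7 to 29.99) and 15.1% (11.8 to 18.8), and 10.7%, 15.3% and 30.9% (26.5 to 35.5). Genes that define these clusters, such as Cma1, Ltb, Cd160, Xcl1 and Cxcr3, differ between the origins too, so the shares and those genes are not separate observations. A cluster of cells with few UMIs, unnamed, held 52.4%, 55.7% and 46.6% of the origins, and a small cycling cluster named for granulocytes 2.57%, 2.31% and 7.42%. The latter had 14, 18 and 32 cells. By contrast, 0, 1 and 10 cells of these origins were rich in granulocyte transcripts (at least 20 UMIs of 6 genes). Most cells of that cluster were thus not rich in them, and leaving the cluster out, as done below, also removes cycling cells. Of the barcodes with each hashtag, 43.4% (ENKP), 45.4% (ALP) and 30.8% (ILCP) passed quality control, with median mitochondrial shares of 10.4%, 10.1% and 13.1% before it.

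ENKP-derived cells had more of the Ly49 receptor genes than ILCP-derived cells. Klra8, the activating receptor Ly49H, was at 696 against 28.1 CPM, 24.7-fold higher (18.7 to 33.4), and Klra4, Ly49D, at 195 against 5.52 CPM, 35.3-fold higher (19.0 to 74.2). Ly49 genes are near-identical copies, so counts of single members are uncertain; summed over the list, ENKP-derived cells had 3189 and ILCP-derived cells 945.1 CPM, a ratio of 3.37 (3.20 to 3.56). Prf1 (1564 against 750.4 CPM, 2.08-fold) and the cell cycle gene Stmn1 (3.58-fold) were also higher. The largest ratios toward ILCP origin were granulocyte genes, S100a9 (6723 against 35.6 CPM, 189-fold), S100a8 (245-fold), Ngp (450.2-fold) and Camp, which rested on 10 of the 431 ILCP-derived cells holding 99.6% of the UMIs of 6 such genes. All 7 measured granulocyte and monocyte markers were lower in the ENKP-derived cells (median log2 −7.56). Of 3635 genes 29 were at least 2-fold higher in ENKP-derived cells and 91 lower; with the hashtag required to hold 80% of a cell's hashtag counts these were 27 and 51, and the ratios of Ngp and Camp were 1.08 and 1.05.

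Without the cluster named for granulocytes (530 against 399 cells) 23 genes of 3619 were at least 2-fold higher and 44 lower. Klra4 (29.9-fold, 16.1 to 63.0), Klra8 (24.6-fold, 18.4 to 33.5), the NK receptor gene Klri2 (9.08-fold, 5.96 to 14.4), Klra3 (5.61-fold), Cma1 (287 against 72.3 CPM, 3.97-fold, 3.25 to 4.89), Klra9 (3.37-fold), the protease inhibitor gene Serpinb9b (3.08-fold), Spp1 (osteopontin; 2.56-fold), Itgam (CD11b; 282 against 127 CPM, 2.21-fold) and Zeb2, a transcription factor of NK maturation (613 against 298 CPM, 2.06-fold, 1.85 to 2.29), were higher in ENKP-derived cells. Lower were the lymphotoxin gene Ltb (58.0 against 293 CPM, 5.04-fold), Cxcr3 (3.18-fold), the receptors Cd226 (118 against 334 CPM, 2.84-fold) and Cd160 (163 against 437 CPM, 2.68-fold), Tnfsf8, the chemokine gene Xcl1 (278 against 698 CPM, 2.51-fold), Cd27 (65.6 against 164 CPM, 2.5-fold), Cd7 (2.47-fold) and Jaml (2.46-fold). Several of these ratios were nearer 1 within clusters. In the mature NK-like cluster the ratio of Itgam was 0.998 (0.798 to 1.26), of Zeb2 1.13 (0.947 to 1.35), of Cma1 1.86 (1.46 to 2.39) and of Xcl1 1.055 (0.7002 to 1.63). In the immature NK-like cluster they were 1.51, 1.72, 1.31 and 0.642, and in the unnamed cluster 2.40, 1.52, 2.37 and 1.12. Ltb had ratios of 0.423 (0.164 to 1.14), 0.355 (0.269 to 0.461) and 0.486 (0.296 to 0.787) in these clusters, in that order, and Klri2 of 3.28 or more in each. Of the 7 measured Ly49 genes 5 were higher and 0 lower, with a median log2 ratio of 2.19, at percentile 100 among matched random lists. Of 12 cytotoxic effectors 10 stayed within 2-fold, with Prf1 at 0.97, Gzma at 0.77 and Gzmb at 0.63, and Gzmm (−2.16) and Tnfsf10 (TRAIL, −1.68) were lower. Cytokines went both ways, with Ccl3 higher (1.27) and Xcl1 (−1.33), Il2 (−2.08) and Ltb (−2.33) lower among 8. Of 21 transcription factors, Zeb2 (1.04) was higher and Tcf7 (−2.41), Bcl11b (−1.13) and Maf (−1.01) lower. Of the 7 measured ILC1 markers 5 were lower and 0 higher (median −1.67).

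The remaining lists were compared between ENKP-derived and ILCP-derived cells in the same way. Of 19 other NK receptors 1 was higher, Klri2 (3.18), and 4 lower, among them Cd226 (−1.50) and Cd160 (−1.42). Homing and adhesion genes had Itgam higher (1.14) and Cxcr3 (−1.67) and Cd27 (−1.32) lower among 18. The 12 cytokine receptors, 8 immediate early genes and 5 interferon response genes stayed within 2-fold, and Myc (−1.24) was the 1 of 14 mTORC1, MYC and glycolysis genes that did not. Of 10 cell cycle genes 1 was higher. With the granulocyte-named cluster kept, 6 of 12 immediate early and 1 of 6 interferon response genes were lower in the ENKP-derived cells, and 3 of 15 cell cycle genes higher.

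**Figure D4:**
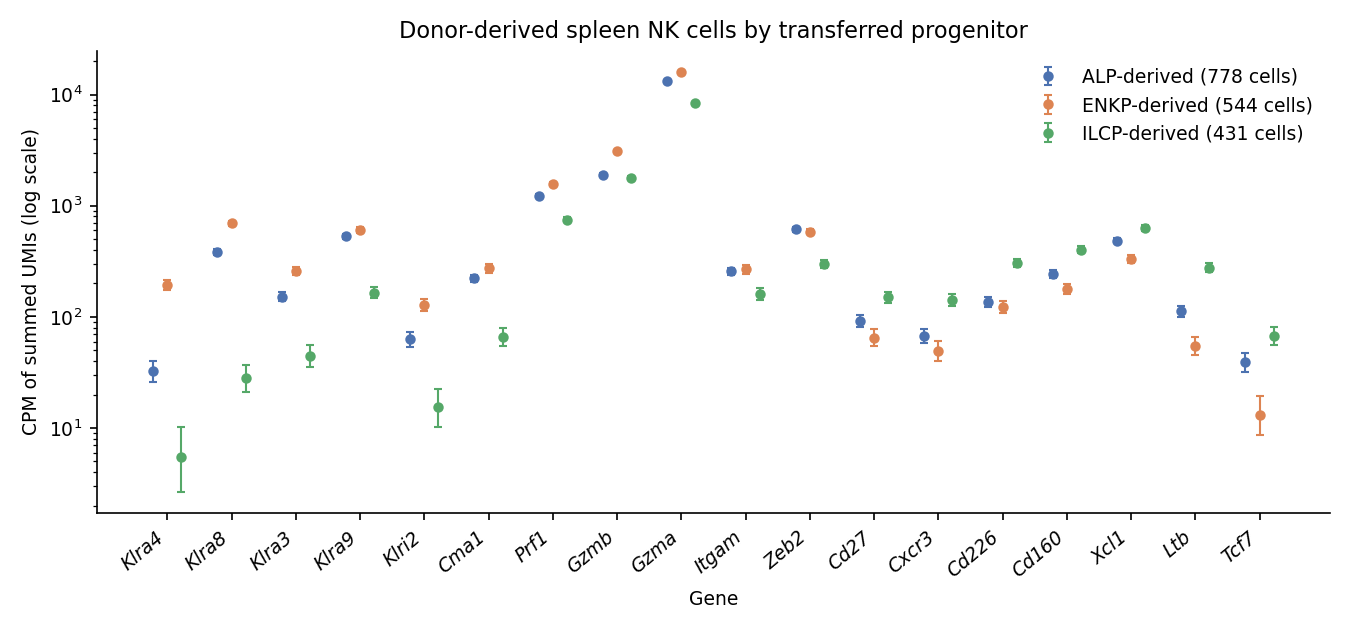
CPM of summed UMIs (vertical log axis) of selected genes (horizontal axis) in spleen NK cells derived from ALP, ENKP and ILCP, with exact Poisson 95% intervals as error bars. Klra8 was at 696 CPM in ENKP-derived, 386 CPM in ALP-derived and 28.1 CPM in ILCP-derived cells.

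ALP-derived cells lay close to ENKP-derived cells. Of 3583 genes 7 were at least 2-fold higher in ALP-derived cells and 3 lower. Ltb was 2.04-fold higher in the ALP-derived cells (112 against 54.9 CPM, 1.64 to 2.57), the T cell gene Cd3g 1.88-fold, Cx3cr1, a chemokine receptor gene of mature NK cells, 1.49-fold and Xcl1 1.46-fold, and Tcf7 had a log2 ratio of 1.57. Klra4 was 6.04-fold lower (32.3 against 195 CPM), Klri2 2.04-fold, Klra8 1.80-fold (386 against 696 CPM), Klra3 1.70-fold, Spp1 1.70-fold and Gzmb 1.62-fold (1908 against 3084 CPM). Of 7 Ly49 genes 2 were lower and 0 higher (median −0.77), and 1 of the 2 measured T cell markers was higher. Against ILCP-derived cells, with the granulocyte-named cluster left out of both (760 against 399 cells), ALP-derived cells had more of Klra8 (13.8-fold, 10.4 to 18.9), Klra3 (3.33-fold), Cma1 (3.23-fold), Klra9 (3.11-fold), Cx3cr1 (2.79-fold), Zeb2 (2.18-fold), and the integrin genes Itga4 (2.15-fold) and Itgam (2.10-fold), and less of Jaml (3.13-fold lower), Ltb (2.45-fold), Cd226 (2.37-fold), Cxcr3 (2.24-fold) and Cd160 (1.84-fold). Of 3631 genes 22 were at least 2-fold higher and 26 lower, against 23 and 72 of 3670 with that cluster kept, where all 7 granulocyte and monocyte markers were lower in the ALP-derived cells (median −7.16). Of 6 Ly49 genes 5 were higher (median 1.69), of 18 homing genes 4 were higher and 1 lower, and of 7 ILC1 markers 5 were lower (median −1.45).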

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

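Of the tests below, those of NK subset shares, of reads shared among Ly49 copies, of doublets and of a mixture were chosen only after the result was seen, as were the hashtag threshold in the ILC progenitor library and the UMI minimum for spleen barcodes.

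A hashtag antibody was counted in the ILC progenitor library, which no comparison uses, and this drew attention. Of its 4100 cells 1672 had at least 500 hashtag counts (40.8%, 95% interval 39.3 to 42.3). The medians were 6156 counts in these and 30 in the others, with 53 cells between 100 and 1000. The share was 40.8% in EILP-like, 43.0% in ILCP-like, 40.9% in ALP-like and 37.4% in ILC2 progenitor-like cells, but higher in granulocyte and monocyte-like cells (54.5%, 43.6 to 65.2) and unnamed cells (60.3%, 48.5 to 71.2). Of 2763 genes at 50 CPM or more, 0 were at least 2-fold higher in the cells with the hashtag and 5 lower. What the hashtag marked is not given in the sources used here, so the library was kept as 1 group.

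Spleen barcodes that failed quality control, which the main comparisons leave out and relaxed quality control takes in part, drew attention because they carried the Ly49 difference too. Among those with at least 300 UMIs (711 ENKP-derived and 970 ILCP-derived), Klra8 was at 415 against 69.1 CPM, a ratio of 6.01 (4.83 to 7.53), Klra4 had a ratio of 4.09 and Ltb of 0.483.

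Klra4 and Klra8 were higher in ENKP-derived than in ILCP-derived spleen cells. Different shares of the spleen clusters would leave Klra8 alike within each. In 3 clusters made without the Ly49 genes, its lowest ratio was 14.3 (9.47 to 22.5). Klra9 and Klra7 had lower ratios: 1.63 and 1.32 in the mature NK-like cluster, and 5.45 and 1.88 in the immature NK-like cluster. In the unnamed cluster they were 1.92 and 1.99. Such clusters cannot separate subsets that differ in Ly49 expression itself, so different shares of those stay open. If reads were only split differently among near-identical copies, the summed list would be alike, but its ratio was 3.37 (3.20 to 3.56). Poorer cells in the ILCP-derived sample do not account for it either, since in cells with at most 5% mitochondrial UMIs thinned to 1000 UMIs the ratio was 17.7 (8.80 to 41.7; 261 against 214 cells). The progenitor of origin may explain the pattern, as a hypothesis only, since the recipient animals are confounded with the origin and it was found and tested on the same data.

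T cell-like cells made up 34.3% of the CD122+ library. Free RNA would reach all classes alike, but at 2000 UMIs per cell 1.29% of EILP-like and ILCP-like cells (5 of 388) had a Cd3d, Cd3e or Cd3g UMI, against 86.3% of T cell-like cells; the name rests partly on these genes, so the low share in the other classes is the part that counts. Doublets with progenitors would hold more UMIs, but the larger T cell-like cluster had a median of 9764 in this library, below 22777 in EILP-like and 18916 in ILCP-like cells. The smaller, cycling T cell-like cluster was not tested. Unthinned, Il2rb, the gene of the sorted marker CD122, was detected in 93.9% of the T cell-like cells of this library. The shares were 84.1% in its EILP-like and 81.3% in its ILCP-like cells. The T cell-like cells thus carried transcripts of the sorted marker. Whether the sort was meant to admit them stays open, since its gates are not given, and no biological explanation was tested.

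ALP-derived spleen cells were set against the other origins, with the granulocyte-named cluster left out of all. The 29 genes used differed at least 2-fold between ENKP-derived and ILCP-derived cells at 100 CPM or more. Genes that the naming rule leaves out were not used. Choosing genes far apart at the ends by itself tends to place another group between them, so lying between is no finding here. If ALP-derived cells were 1 mixture of the cell types of both, each gene would give the same fraction, but 8 of the 29 genes (27.6%) excluded the common fraction of 0.726 in 1000 resamplings of cells. In 20 simulated true mixtures (0.7 of cells from ENKP, 200 resamplings) a median of 3.45% and at most 10.3% of genes did so. These mixtures and their ends were random parts of the ENKP-derived and ILCP-derived cells, so they held fewer cells than the real groups. They also came from the cells that chose the 29 genes, unlike the ALP-derived cells. The simulated shares are therefore not a like comparison for the 27.6%. Klra4 (0.161), Klri2 (0.400), Zfp512 (0.430), Klrb1f (0.455) and Klra8 (0.545) lay to the ILCP side of the common fraction and Cd226 (0.894) to the ENKP side. Zeb2 (1.12, 0.872 to 1.48) and Jaml (1.15, 0.913 to 1.54) lay past the ENKP value, with intervals that include it. The 29 genes were chosen from the same cells that set the ends, which can shift their fractions. The share of 27.6% therefore does not decide whether ALP-derived cells are 1 mixture of both. Mixtures that include a further cell type stay open too, as does a difference between recipient animals.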

How the results depend on the processing

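No paired analysis was possible because each group is 1 library or 1 hashtag, and for the same reason leaving out each animal in turn and a replicate block gave no value. Relaxed quality control, leaving out cells rich in granulocyte transcripts, size factors and per-cell means for the spleen, and all alternatives within classes and in cluster 5 were chosen after seeing the data.

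Of 78 counts of genes under alternatives 24 moved by more than 1.5 times, as did 28 of 66 class shares and 10 of 12 main regulator shares beyond their intervals, and 0 of 24 shares of mature NK-like and immature NK-like spleen cells. The other spleen names were less stable: with the 80% hashtag rule the large cluster of cells with few UMIs (827 cells), otherwise unnamed, took the granulocyte and monocyte name. Of 1866 values of named genes 32 reversed and 1543 stayed within 1.5-fold, and of 839 list medians 12 reversed and 305 moved. Of the other regulator shares 520 of 768 moved.

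Without an expression floor the counts were 1282 (CD122+ against ILC progenitors, 69 with the floor), 1718 (CD122+ against NK cells and ILC1s, 112), 2721 (ILC progenitors against NK cells and ILC1s, 289), 1620 (ENKP against ILCP origin, 120), 855 (ALP against ENKP, 10), 1507 (ALP against ILCP, 95), 1687 (EILP-like, 75), 1246 (ILCP-like, 11) and 1824 (cluster 5, 99), because genes with few counts then enter. Depth set limits too: thinned to 2000 UMIs the counts were 174 (EILP-like), 137 (ILCP-like) and 332 (cluster 5), and thinned to 1000 UMIs 32 for ALP against ENKP. Thinning leaves fewer UMIs per gene by construction, and counts of genes within classes rest on few cells.

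Between CD122+ progenitors and NK cells and ILC1s the count was 232 without other lineages. The interferon response median of −0.56 reversed to 0.32 with thinning, 0.37 with the mean of per-cell CPM and 0.0349 for members at 100 CPM or more; the cause was not tested. Thinning moved the split of 35 higher and 77 lower to 79 and 73. In cluster 5 TMM factors moved 37 higher and 62 lower to 24 and 82. TMM factors moved the median of all genes from 0.04 to −0.09 for CD122+ against ILC progenitors, from 0.05 to −0.15 against NK cells and ILC1s (−0.14 with size factors) and from 0.08 to −0.03 in cluster 5, and size factors that of ILC progenitors against NK cells and ILC1s from 0.00 to −0.10.

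For ENKP against ILCP origin the count of 120 was 78 with the 80% hashtag rule, 67 without other lineages or without cycling clusters (the same cells) and 79 with relaxed quality control. The granulocyte genes reversed, because 10 ILCP-derived cells carried them. Ratios under the 80% rule were 1.08 (Ngp), 1.05 (Camp), 2.69 (Retnlg) and 1.35 (Wfdc21); without other lineages or cycling clusters 1.21 (Camp), 1.001 (S100a8), 1.19 (S100a9) and 1.33 (Wfdc21); and without cells rich in granulocyte transcripts 1.01 (Camp), 1.10 (S100a8), 1.13 (S100a9) and 1.31 (Wfdc21). Of those 10 cells 1 had 80% of its hashtag counts on 1 hashtag (median 69.6%), against 397 of the other 421 (median 91.4%). The cytokine receptor median reversed to −0.0137 at the stricter hashtag quantile, −0.0365 without other lineages or cycling clusters, −0.11 thinned to 1000 UMIs and −0.13 with relaxed quality control, where other NK receptors were at −0.0181; the cause was not tested. The Ly49 median of 2.32 (interval 1.87 to 2.74) did not leave its interval in 3 alternatives: members at 100 CPM or more, the mean of per-cell CPM, and TMM factors. The TMM factors were nearly equal, 0.996 (ENKP) and 0.992 (ILCP), so they could hardly move it. The hashtag rules, thinning and relaxed quality control were not set against this interval.

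For ALP against ENKP the count of 10 was 4 with relaxed quality control, and the immediate early median reversed to −0.0267 at the stricter hashtag quantile. For ALP against ILCP the count of 95 was 59 with the 80% rule, 48 without other lineages or cycling clusters, 62 with relaxed quality control and 63 without cells rich in granulocyte transcripts. Its reversed ratios were 1.90 (Retnlg), 1.32 (Camp) and 1.39 (Ngp) with the 80% rule; 1.54 (Camp), 1.41 (S100a8), 1.14 (Ngp), 1.81 (Lyz2) and 3.25 (Cybb) without other lineages or cycling clusters; and 1.27 (Camp), 1.39 (S100a8) and 1.17 (Ngp) without cells rich in granulocyte transcripts. The mTORC1, MYC and glycolysis median reversed to 0.0324 with relaxed quality control. In ILCP-like cells the other NK receptor median reversed to −0.11 with thinning. The cause was not tested for these medians.

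ALP-like cells of the ILC progenitor library (44.7%) were 47.1% at resolution 0.5, 40.9% at 1.5, 46.4% with 4000 variable genes, 35.9% without cell cycle genes and 46.5% with doublets kept. EILP-like cells there (11.7%) were 10.8% without cell cycle genes, 9.95% with doublets kept and 12.8% at 5% mitochondrial UMIs. In the CD122+ library EILP-like cells (17.5%) were 15.2% at resolution 0.5, 14.96% with 4000 variable genes and 15.2% with doublets kept, immature NK-like cells (13.2%) 9.30% at resolution 0.5, and T cell-like cells (34.3%) 9.78% with doublets kept, where the larger cluster tied between the T cell and immature NK names. In the NK and ILC1 library mature NK-like cells (43.4%) were 47.8% at resolution 0.5, 47.8% at 1.5, 48.0% with 4000 variable genes, 47.8% without cell cycle genes, 48.5% with doublets kept and 48.7% at 5% mitochondrial UMIs, and immature NK-like cells (12.2%) 3.64%, 7.97%, 7.76%, 7.25%, 7.79% and 7.62%. ILC1-like cells (27.2%) were 31.3% at resolution 0.5, 25.9% at 1.5 and 1.57% at 5% mitochondrial UMIs, where the large cluster went unnamed for its leading genes. The cause of the other shifts was not tested.

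In EILP-like cells of the CD122+ library Il2rb (30.4%) was detected in 84.1% unthinned, 49.8% at 4000 UMIs and 7.96% with at least 2 UMIs, Zbtb16 (32.8%) in 70.1%, 40.7% and 8.46%, and Eomes (5.97%) in 16.4% unthinned and 1.49% with at least 2 UMIs. Tbx21 (0.498%) was detected in 0 cells at 4000 UMIs and with at least 2 UMIs. Detection follows the UMIs per cell by construction.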

Other observations

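Of the tests below, the correlation with the bone marrow difference was chosen before its result was seen, and the comparisons between classes of 1 library after the clusters were seen.

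Mature NK-like and ILC1-like cells were compared within the NK and ILC1 library. All 9 measured interferon response genes were lower in the mature NK-like cells (median log2 ratio −2.49), among them Ly6a (−7.37), Ifit3 (−5.30), Ifit1 (−4.82) and Isg15 (−2.55). A cluster of 83 ILC1-like cells in this library was led by interferon response genes. Those cells may carry part of the difference, but how much was not measured. Of 13 mTORC1, MYC and glycolysis genes 2 were lower, Myc (−2.37) and Odc1 (−1.93), and 0 higher. In the CD122+ library 19 of 20 cell cycle genes were higher in EILP-like than in ILCP-like cells (median 2.63; Cdk1 6.45, Mki67 5.50), where the EILP name takes in a cycling cluster and the ILCP name none, and 3 of 4 cytokine genes were lower (median −2.51).

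The genes that differ between ENKP-derived and ILCP-derived spleen cells may lie along the difference of mature NK-like from ILC1-like bone marrow cells. The spleen ratios used here leave out the granulocyte-named cluster. Across 1365 genes at 100 CPM or more in both comparisons, Spearman's rho of the log2 ratios was 0.487 (Pearson's r 0.706; rho 0.481 without the Ly49 genes), and 24 of 24 genes at least 2-fold apart in the spleen had the same direction in bone marrow. Some of these genes, such as Cma1, Itgam, Zeb2 and Cxcr3, are also markers that named the bone marrow classes. Their bone marrow direction was thus largely set by the naming, and the correlation without such markers was not taken. The correlation is across genes, which are not independent replicates. Differences in subset shares between the origins enter it and were not separated. It leaves open whether ILCP-derived cells are like ILC1s or less mature NK cells, since immature NK cells and ILC1s share markers.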
